A study of Mus musculus with 2 samples.

How the data were processed

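The samples were H3K27ac ChIP-seq libraries from mouse facial prominences at embryonic day 12.5, 1 group with 2 biological replicates from pools of 120 and 88 embryos, with DNA fragments of 300 to 500 bp per the labels. Peaks were called by the authors for each replicate and also on the pooled reads of both, each against control libraries, per the labels and per the file headers. A replicated list was derived by the authors from the pooled list and both replicates' lists. Coordinates are on mm10 (GRCm38) and are given 1-based. The peak caller, the aligner, their versions and the overlap rule behind the replicated list are not given in the sources used here.

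Each peak has an enrichment, a ratio over control as the authors' caller gave it, whose exact formula is not given in the sources used here. Each peak also has −log10 p and −log10 q values, deposited by the authors on that scale. The lists reach down to a −log10 q of 0.369 in replicate 1 and 0.358 in replicate 2. The deposited score, which ends at 1000, was read only to check the columns. Enrichment was used to describe, rank and filter peaks within a list and to rank the same peaks in 2 lists, never as a level compared between libraries. The lists hold no read counts, so depth is unknown and no interval for depth is given. Peaks, genes and chromosomes are not replicates, and p-values over genes describe a peak list.

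Overlapping intervals within a list would have been merged; none overlapped. Peaks were called shared with at least 1 bp of overlap, and shares were compared with 100 random placements on the same chromosome. Transcript starts came from the basic set of GENCODE mouse release 21 (its M series), with 21911 protein-coding genes on chromosomes with at least 1 peak. A promoter peak lay within 1 kb of any protein-coding transcript start of a gene, and a distal peak more than 2.5 kb from every such start. Starts of non-coding genes were not counted, so distal peaks can include promoters of such genes. The 24 gene lists cover facial mesenchyme regulators, mandibular patterning, Hox clusters, facial epithelium, cartilage, bone, extracellular matrix and mesenchyme, skeletal muscle, endothelium, erythroid and myeloid cells, peripheral neurons and glia, forebrain, heart, liver, adult lymphocytes, the hedgehog, BMP, WNT, FGF and retinoic acid pathways, orofacial cleft genes, housekeeping genes, and olfactory and vomeronasal receptors. Some genes are in more than 1 list, so the results of different lists are not independent, and no test left shared genes out. Promoter shares were tested by a two-sided Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Mean numbers of distal peaks within 100 kb of the main start were set against 10000 random lists matched on promoter state and on 5 bins of gene density, two-sided, with the same adjustment.

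Motif matches on both strands were counted for 24 consensus strings in distal peaks and in windows of the same width on the same chromosome, outside all peaks, with GC content within 2 percentage points; 99.5% of the peaks could be matched. Each string reversed without complement served as a control, and the spread is that over the 19 autosomes. Pairs of an E-box and TAATTA were counted at each spacer from 0 to 20 bp in both E-box orientations, 42 arrangements in all. Large distal domains were distal peaks joined when 12.5 kb or less apart and ranked by the sum of width times enrichment.

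Lists, motifs, tests, thresholds and the naming rule were fixed before the data were examined, except where a choice is said to have been made later. Named by that rule were, per list, up to 5 members with the most acetylated sequence within 100 kb and up to 3 without a promoter peak (all members for Hox and mandibular lists), the nearest genes of the 25 first domains, the 10 strongest distal peaks, and the 5 strongest peaks found in each replicate alone. Genes outside the rule are said to have been chosen after their values were seen. The rule for calling a motif was set after the ratios were seen.

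Alternatives were an overlap of 50% of the own length or of both peaks, −log10 q of at least 2 or 10, the 20000 peaks of highest enrichment, each replicate's own list in place of the replicated one, the pooled list, a promoter distance of 2.5 kb, 1 main start per gene, windows of 50 and 250 kb, unmatched random lists, matching on CpG as well, 500 bp around the summit, windows 10 kb from each peak, joining at 5 kb and ranking by covered length. Added after seeing the data were the restriction to replicated peaks found in both replicates' lists, counting list members within 200 kb of each other once, and the spacing scan on the other filters.

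The promoter-list, distal-list and motif-density steps were tested on simulated data; the spacing scan, the domains, the retention and the chromosome comparison were not. In simulated promoter lists of 20 genes, 2.5% passed the threshold when the true share was 50%, 61.7% when it was 80% and 100% when it was 95%. In simulated distal lists of 20 genes, 2.08% passed with no difference, 57.5% with a 2-fold and 98.3% with a 3-fold mean, and the recovered folds were 1.96 and 2.83. Simulated values were drawn independently for each gene, so these shares do not cover lists whose neighbouring members share peaks. Planted motif densities of 1.3-fold and 2-fold were recovered as 1.25 and 2.0. Overlap counts equalled those of bedtools. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1.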

Results

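H3K27ac, an acetylation mark on histone H3 found at active promoters and enhancers, was mapped by ChIP-seq in the facial prominences of B6NCrl mouse embryos at day 12.5. The facial prominences are the swellings of neural crest mesenchyme and covering epithelium that build the face and palate. The design held 1 group with 2 biological replicates, from pools of 120 and 88 embryos of mixed sex. No second tissue, stage or treatment was included, so the comparisons run between the replicates, and between gene groups within the peak lists. Replicate 1 had 95451 peaks covering 40.5 Mb of the mm10 genome, and replicate 2 had 93080 peaks covering 44.1 Mb. The list called on the pooled reads had 121738 peaks over 59.7 Mb, and the replicated list kept 50948 of these over 42.2 Mb. The lists hold no read counts, so the depth of each library is unknown and no interval that needs it is given.

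Acetylated regions at promoters were found in both replicates more often than distal ones. In replicate 1, 81.8% of promoter peaks and 44.4% of distal peaks overlapped a peak of replicate 2; in replicate 2 the shares were 79.4% and 43.0%. Promoter peaks of the replicated list were also wider (median 849 against 510 bp) and stronger (median enrichment 6.10 against 3.55). The shares were not matched on width or strength, so their part in the difference was not tested. The highest peaks found in replicate 1 alone lay at Wdr27 (chromosome 17, 14942755 to 14943070, enrichment 7.71), Vapb (7.17) and Podxl2 (6.92). They lay 54, 23 and 45 bp from a transcript start. An intergenic peak 194 kb from Sox4 (6.69) and an intron peak of Tsc22d1, 8.55 kb from a start (6.57), followed. The highest in replicate 2 alone lay at transcript starts of 6030458C11Rik and Tprgl, in coding exons (both 8.11). Next came peaks whose nearest starts were those of Rdh14 (7.34, 182 kb away), Nepro (7.34, 6.74 kb) and Kcnma1 (7.33, 223 kb). These values are far below the highest of either list, 46.9 in replicate 1 and 54.3 in replicate 2.

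Over all peaks, 51.7% of replicate 1's peaks (49348) overlapped a peak of replicate 2 by at least 1 bp, and 49.9% of replicate 2's peaks (46444) overlapped a peak of replicate 1. Random placements on the same chromosomes gave 3.23% ± 0.055 and 3.29% ± 0.059 (SD over 100 placements), so the observed shares were 16-fold and 15.2-fold higher. Of the 10496 peaks of replicate 1 with a −log10 q of at least 10, 99.9% met some peak of replicate 2, and 15 did not. Of the 12003 such peaks of replicate 2, 99.6% met a peak of replicate 1, and 49 did not. Over 42397 pairs of overlapping peaks the enrichment values ranked alike with Spearman's rho of 0.671, a description across peaks, which are not independent replicates. The shares depended on the overlap asked for: with at least 50% of both peaks covered, 28.9% and 29.7% were shared. They were 89.2% and 76.2% when only peaks with a −log10 q of at least 10 were kept in both lists.

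Promoters of Tnrc18 and Brd2, a bromodomain reader of acetylated histones, held some of the highest enrichment values of the replicated list, 56.0 and 52.5; these genes were chosen after their values were seen. Every peak of the replicated list was identical to a peak of the pooled list, and 41.9% of the pooled peaks were kept. With the pooled peaks ranked by enrichment and split into 10 groups of equal size, the share kept went from 4.51% in the lowest group to 100% in the highest. Of the replicated peaks, 80.3% (40916) overlapped a peak in both replicates' own lists, 4226 in replicate 1's alone, 5385 in replicate 2's alone, and 421 in neither. The 10032 peaks without a peak in both lists had a median enrichment of 3.11, against 2.56 for the 70126 pooled peaks that also lacked such support and were dropped. Among pooled peaks with a −log10 q of at least 10, 99.9% were kept.

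**Figure D1:**
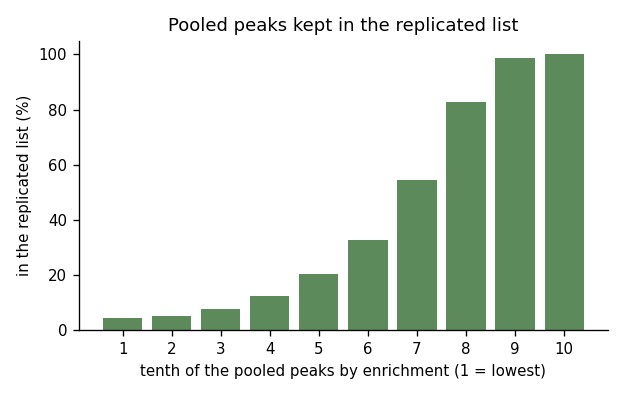
Percent of pooled peaks kept in the replicated list (vertical axis) in 10 groups of equal size by enrichment (horizontal axis, lowest to highest). Bars go from 4.51% in group 1 to 54.4% in group 7 and 100% in the highest.

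Promoters held 26.6% of the replicated peaks (13549), introns 38.8%, exons 3.01% and intergenic sequence 31.6%. Random placements put 3.05% ± 0.08 (SD over 100 placements) at promoters, so the share was 8.71-fold higher there, and 0.55-fold in intergenic sequence. Promoter peaks had a median enrichment of 6.10 and a median width of 849 bp; the 35423 distal peaks, those more than 2.5 kb from any protein-coding transcript start, had 3.55 and 510 bp. Of 21911 protein-coding genes, 11221 (51.2%) had a promoter peak, and 11032 had one in both replicates' own lists. The promoter share was 18.8% in replicate 1's own list, 18.7% in replicate 2's and 15.5% in the pooled list, and 50.9% among replicated peaks with a −log10 q of at least 10. The fold over random placements was 7.11 in replicate 1, 6.93 in replicate 2 and 5.73 in the pooled list.

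Chromosome X held fewer acetylated regions per length than any autosome. The replicated list had 4.34 peaks per Mb on X, against a median of 20.1 over the 19 autosomes, from 15.0 on chromosome 14 to 34.1 on chromosome 11. Both replicates' own lists showed it, with 6.57 and 6.65 peaks per Mb on X against autosome medians of 37.9 and 37.6. Phex on X, which acts in bone mineralization, had no promoter peak and 0 distal peaks, as had Arx, a forebrain regulator. Tbx22, an X-linked cleft palate gene, and Chrdl1, a BMP antagonist on X, had a promoter peak in replicate 1's own list alone. Chromosomes are not replicates, so no test was run on them.

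**Figure D2:**
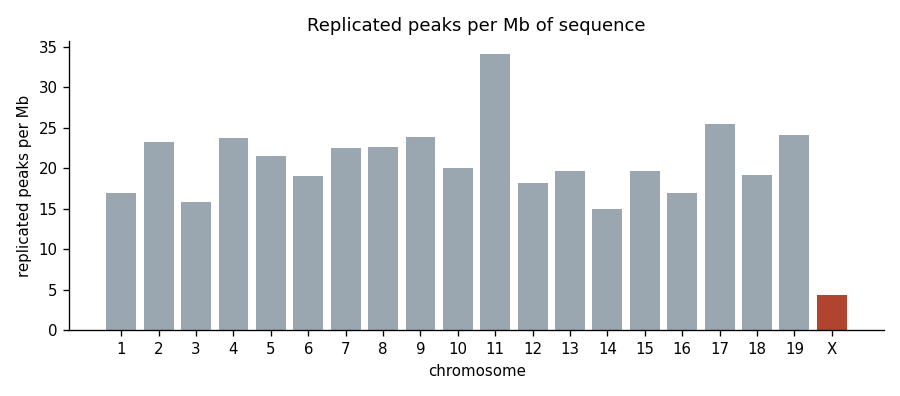
Replicated peaks per Mb of sequence (vertical axis) for each chromosome (horizontal axis). Chromosome X, in red, stands at 4.34, and the 19 autosomes lie between 15.0 and 34.1.

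Transcription factor genes that pattern the facial mesenchyme carried acetylated promoters throughout. All 38 facial mesenchyme regulators had a promoter peak, in the replicated list and in each replicate's own list, against 51.1% of other protein-coding genes (adjusted p = 1.22e-10, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 24 lists, as for all promoter values of lists here). Alx4, a homeodomain gene needed for skull and midface development, had a promoter enrichment of 40.0, Prrx2, a homeodomain gene of limb and face mesenchyme, 21.6, and Mn1, a palate gene, 20.1. Snai1, a driver of epithelial-mesenchymal transition, had 13.7 and Six2 had 14.5. All 24 genes of the extracellular matrix and mesenchyme list had a promoter peak in the replicated list and in both replicates' lists (Fisher's adjusted p = 8.24e-07), among them Nfib (28.8), Twist2 (16.3) and the collagen gene Col1a1 (7.97). The 20 housekeeping genes, which served as a control, all had one too (Fisher's adjusted p = 8.42e-06), with Actb at 43.1.

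Hox genes, which pattern the trunk and hindbrain and are silent in the neural crest of the face, were nearly free of promoter peaks. Of 39 Hox genes, 3 had a promoter peak (7.69%; Fisher's adjusted p = 8.79e-08): Hoxa2 with an enrichment of 8.44, Hoxb2 with 4.06 and Hoxa1 with 3.3. Hoxa1 and Hoxa2 had one in both replicates' own lists and Hoxb2 in replicate 2's alone. Replicate 1's own list held 5 Hox promoters and replicate 2's 8, of which 2 were in both. The share was 2.56% among peaks with a −log10 q of at least 10 and 20.5% in the pooled list, and it stayed below that of other genes at each setting tried. Neighbouring genes of a Hox cluster are not independent, so the Fisher's p here may be too small.

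Of the 11 genes that pattern the lower jaw, 9 had a promoter peak, a share of 81.8% that did not pass the test (Fisher's adjusted p = 0.106). Ednra, the endothelin receptor through which the lower jaw is specified, had 19.8, Dlx6 16.3, Gsc 15.8, Dlx5 11.6, Hand2 9.69, Barx1 7.63, Mef2c 6.41, Dlx4 4.03 and Dlx3 3.87. Edn1, the ligand of Ednra, and Hand1 had a promoter peak in replicate 2's own list but not in replicate 1's. In replicate 2's list all 11 had a peak and the share passed the test (Fisher's adjusted p = 0.00324, from 0.00324 to 0.268 over the alternatives), and it also passed in the pooled list (adjusted p = 0.0484).

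Genes of the BMP, hedgehog, FGF and WNT pathways, which act in facial growth, had promoter peaks more often than other genes, and those of the retinoic acid pathway did not pass. The BMP pathway had 18 of 21 (85.7%, Fisher's adjusted p = 0.0042), with Smad7 at 40.0, Id3 at 25.3 and Smad6 at 17.4; Grem1, an antagonist, had none in either replicate's list, Chrdl1 had a peak in replicate 1's own list alone, and Bmp2, a ligand, had a peak in both replicates' own lists but not in the replicated list. The hedgehog pathway had 12 of 14 (85.7%, Fisher's adjusted p = 0.0227), with Gas1, a coreceptor, at 38.0 and Ptch1, the receptor and a target of the pathway, at 34.1; Shh, the ligand, had none in either replicate's list, and Hhip had a peak in replicate 2's own list alone. The FGF pathway had 15 of 18 (83.3%, Fisher's adjusted p = 0.0144), with Fgfr2 at 23.7 and Dusp6 at 22.4; of the ligand genes absent from the replicated list, Fgf8 and Fgf15 had a peak in replicate 2's own list and Fgf3 in neither. The WNT pathway had 19 of 24 (79.2%, Fisher's adjusted p = 0.0139), with Fzd2 at 39.1 and Tcf7l2 at 33.9; Wnt3, Wnt9b and Tcf7 (chosen after its value was seen) had none in either replicate's list, Wnt5b had a peak in replicate 2's alone, and Wnt11 in both replicates' lists but not in the replicated list. The retinoic acid pathway had 11 of 18 (61.1%, Fisher's adjusted p = 0.579), with its receptors Rarg at 29.9, Rara at 27.2 and Rxra at 24.7, and without Aldh1a1, Cyp26a1 and Cyp26c1. The hedgehog and FGF calls were lost in replicate 1's own list (Fisher's adjusted p = 0.0518 and 0.0918; 0.00994 to 0.0518 and 0.00139 to 0.0918 over the alternatives), and the FGF call also among the 20000 peaks of highest enrichment. The WNT call was lost when only replicated peaks found in both replicates' lists were kept, an alternative chosen after seeing the data (Fisher's adjusted p = 0.06; 0.0064 to 0.06 over the alternatives).

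Genes mutated in or associated with orofacial clefts had promoter peaks in 35 of 40 cases (87.5%, Fisher's adjusted p = 8.25e-06). Ptch1, Mn1, Tbx3 (19.7), Fgfr1 (16.3) and Ctnnd1 (15.3) had the most acetylated sequence around them. Of these, Mn1 is also a listed facial mesenchyme regulator, Ptch1 a hedgehog gene and Fgfr1 an FGF gene. The cleft result is thus not independent of those lists. The cleft genes without one were Irf6, Grhl3 and Trp63, regulators of surface epithelium, and Wnt9b and Tbx22; Irf6, Grhl3 and Trp63 had a promoter peak in replicate 2's own list alone, and Irf6 and Grhl3 are named outside the naming rule, after their values were seen.

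Markers of facial epithelium stood near the level of all genes, with 13 of 25 (52%, Fisher's adjusted p = 1). The keratin genes Krt8 and Krt18 had promoter enrichments of 3.20 and 3.29, and the claudin genes Cldn4 and Cldn3 4.48 and 3.10. Trp63, the master regulator of stratified epithelium, and Dsp had a promoter peak in replicate 2's own list alone; Shh had none in either. Replicate 1's list held 14 of these promoters and replicate 2's 19. Among peaks with a −log10 q of at least 10 the share was 16%, below that of other genes (Fisher's adjusted p = 0.0229, from 0.0229 to 1 over the alternatives).

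Skeletal lineages were partly marked. Of 15 cartilage genes, 10 had a promoter peak (66.7%, Fisher's adjusted p = 0.405), with Col2a1, the main cartilage collagen, at 11.9 and Col9a2 at 10.6, and without Acan, Snorc and Matn1, the last of which had a peak in replicate 1's own list. Of 13 bone genes, 7 had one (53.8%, Fisher's adjusted p = 1), among them Dlx5, Col1a2 (8.03), Alpl (4.56) and Sp7 (3.75), an osteoblast regulator; the mineralization genes Ibsp and Spp1 had none.

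Among markers of other cell types that the dissected tissue can hold, endothelium had 10 of 16 (62.5%, Fisher's adjusted p = 0.577), with Fli1 at 12 and Ramp2 at 6.73, and 87.5% in the pooled list (adjusted p = 0.0332, from 0.0332 to 1 over the alternatives). Among peaks with a −log10 q of at least 10 the endothelium share was 25%, against 40.4% of other genes. Peripheral neurons and glia had 10 of 18 (55.6%, Fisher's adjusted p = 0.89), with the glial genes Erbb3 at 8.18, Mpz at 6.34 and Sox10 at 4.07; among peaks with a −log10 q of at least 10 the share was 22.2%. Skeletal muscle had 7 of 16 (43.8%, Fisher's adjusted p = 0.711), with Tbx1, a regulator of head muscle, at 5.83, and without Myf6 and Myod1, the last of which had a peak in replicate 2's own list; the share was 68.8% in the pooled list and 18.8% among peaks with a −log10 q of at least 10. Forebrain had 7 of 19 (36.8%, Fisher's adjusted p = 0.358), with Bcl11b at 23.3, Emx2 at 10.4 and Six3 at 7.35; replicate 1's own list held 11 forebrain promoters (57.9%) and replicate 2's 8. The erythroid list had 4 of 15 (26.7%, Fisher's adjusted p = 0.106), with Klf1 at 6.41 and Nfe2 at 4.47. Replicate 1's own list held 7 erythroid promoters and replicate 2's 3, and the share passed the test in replicate 2's list alone (20%, Fisher's adjusted p = 0.0124, from 0.0124 to 0.732 over the alternatives). The globin genes Hbb-bs, Hbb-bt and Hbb-bh1 had neither a promoter nor a distal peak. Within 100 kb of their starts, 0 bp were covered in the replicated list and in each replicate's own list. Near-identical copies of globin genes can lose reads in alignment, so the absence at the genes themselves is uncertain. Whether such a loss reaches across the whole window was not tested.

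Myeloid genes had fewer promoter peaks than other genes (2 of 15, 13.3%, Fisher's adjusted p = 0.00754): Cd68, a macrophage gene, with 3.19, and Aif1 with 4.22, which replicate 2's own list lacked. Lists for organs outside the face were lower as well. The heart list had 2 of 15 (13.3%, Fisher's adjusted p = 0.00754), the adult lymphocyte list 2 of 18 (11.1%, adjusted p = 0.0017), and the liver list 1 of 18 (5.56%, adjusted p = 0.000186), Foxa3 at 4.53. The own lists of replicates 1 and 2 held 3 and 2 myeloid promoters, 3 and 3 of heart, 2 and 4 of lymphocytes (22.2% in replicate 2) and 1 and 1 of liver, and each share passed the test there. Myh7, a myosin gene of heart and slow muscle, had 5.48, and Cd79b, a B-cell gene, 3.13. Of 1462 olfactory and vomeronasal receptor genes, a control family of repressed genes, 2 had a promoter peak (0.14%), against 54.9% of other genes, with a p too small for the software to represent.

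**Figure D3:**
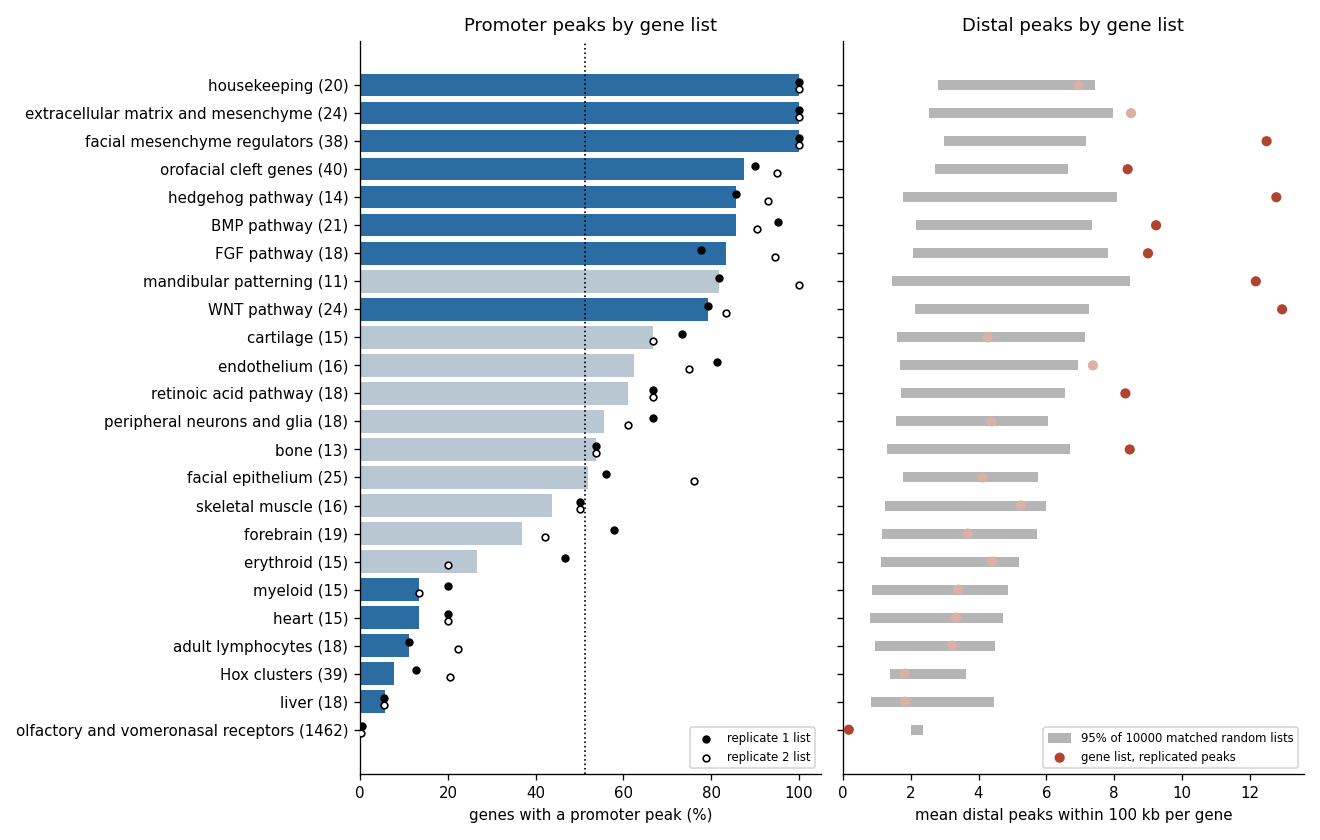
Left, percent of each list's genes with a promoter peak in the replicated list (bars, dark where the adjusted p passed 0.05) and in each replicate's own list (points), with the share of other genes as a dotted line; right, mean number of distal peaks within 100 kb (points, dark where passed) against the central 95% of 10000 matched random lists (grey bars). The list of facial mesenchyme regulators reaches 100% on the left and 12.5 on the right, where its random lists have 2.97 to 7.18.

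Facial mesenchyme regulators and genes of the WNT and hedgehog pathways had more distal acetylated regions around them than matched genes, as had the genes patterning the lower jaw. Facial mesenchyme regulators had 12.5 distal peaks on average within 100 kb, against 4.90 in random gene lists matched on promoter state and gene density (95% of lists 2.97 to 7.18). The WNT pathway had 13.0 against 4.37, and the hedgehog pathway 12.8 against 4.42. For these 3 lists p was 0.0002, the smallest that 10000 random lists can give, and the adjusted p was 0.0012. Each replicate's own list gave 21.5 and 21.8 for the mesenchyme regulators, 21.2 and 22.7 for WNT and 22.9 and 23.4 for hedgehog.

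Alx4 had 47 distal peaks within 100 kb of its start, Prrx2 35, Mn1 34, Snai1 19 and Six2 14. Prrx2 had the most acetylated sequence in this window, 55497 bp. In the WNT list, Wnt11 had 35 distal peaks without a promoter peak in the replicated list, Ror2 had 28, Tcf7l1 25 and Tcf7l2 22. In the hedgehog list, Boc had 33, Gas1 32, Cdon 31, Sufu 20 and Ptch1 19. Shh had 0, where the 2 replicates' own lists had 2 each. Genes patterning the lower jaw had 12.2 against 4.25 (permutation adjusted p = 0.0064), with Barx1 at 23, Ednra at 21, Dlx4 at 20 and Dlx5 and Dlx6, which share a window, at 12; Edn1 had 0.

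Other lists above their matched lists were bone with 8.46 against 3.54 (permutation adjusted p = 0.0171), where Alpl had 23 and Col1a1 19, and the cleft genes with 8.40 against 4.48 (permutation adjusted p = 0.0064). Both share genes with the lists above, such as Dlx5 in bone and Mn1 in the cleft list. BMP genes had 9.24 against 4.37 (permutation adjusted p = 0.0103), where Smad7 had 36, Smad6 27 and Id1 25. FGF genes had 9.0 against 4.50 (permutation adjusted p = 0.0293), where Fgfr2 had 28 and Etv4 18. Retinoic acid genes had 8.33 against 3.75 (permutation adjusted p = 0.0144), where Rxra had 27, Stra6 23 and Rara 19. Olfactory and vomeronasal receptors were the list below its matched lists, with 0.172 against 2.18 (p = 0.0002, the smallest possible; permutation adjusted p = 0.0012).

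The remaining lists did not pass. Extracellular matrix and mesenchyme genes had 8.50 against 4.89 (permutation adjusted p = 0.0515), endothelium 7.38 against 3.85 (0.0572) and housekeeping genes 6.95 against 4.90 (0.203). Skeletal muscle had 5.25 against 3.21 (0.231), erythroid genes 4.40 against 2.90 (0.287), peripheral neurons and glia 4.39 against 3.47 (0.494), cartilage 4.27 against 3.93 (0.761) and facial epithelium 4.12 against 3.51 (0.589). Forebrain had 3.68 against 3.03 (0.589), where Bcl11b alone had 31, myeloid genes 3.4 against 2.53 (0.479), heart 3.33 against 2.40 (0.479), adult lymphocytes 3.22 against 2.43 (0.479), liver 1.83 against 2.33 (0.706) and Hox genes 1.82 against 2.41 (0.479). The FGF call was lost with windows of 50 kb and 250 kb (permutation adjusted p = 0.145 and 0.108; 0.0032 to 0.145 over the alternatives), the BMP call at 250 kb (0.0541; 0.0024 to 0.0541), and the retinoic acid call among peaks with a −log10 q of at least 10 and among the 20000 of highest enrichment (0.0882 and 0.0772; 0.00528 to 0.0882). The Hox list passed below its random lists in both of these sets, with 0.0256 against 0.628 at a −log10 q of at least 10 (permutation adjusted p = 0.0016; 0.0012 to 0.759), and the matrix and endothelium lists passed above theirs. These 3 lists also passed in replicate 2's own list (Hox permutation adjusted p = 0.0276), against unmatched random lists (0.0336) and, an alternative chosen after seeing the data, in replicated peaks found in both replicates' lists (0.0182). Neighbouring Hox genes share windows while random lists draw single genes, so the Hox p-values may be too small. Counting neighbours once was tried only on the reported replicated list, where the Hox list did not pass. The matrix list passed in the pooled list and at 50 kb too, the housekeeping list against unmatched random lists, and the myeloid list at 250 kb (permutation adjusted p = 0.0459; 0.0459 to 1 over the alternatives).

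Ranked by the sum of width times enrichment, the first distal domain lay beside Prrx2. It ran from 30586616 to 30797194 on chromosome 2, spanned 211 kb with 51 replicated peaks, and had Cstad as its nearest gene start. The next ran from 50908424 to 51089683 on chromosome 6, with 85 peaks over 181 kb that overlap no protein-coding gene; the nearest start, of Npvf, lay 254 kb away. Domains ranked 3 and 5 lay within Dnm3 on chromosome 1 and covered 51803 and 59288 bp. The domain ranked 5 overlapped Dnm3os, Mir199a-2 and Mir214, non-coding genes of mesenchyme that were chosen after their positions were seen. Further domains in the first 10 overlapped Tnnt3, Sorl1, Ddc and Sulf2; the other 2 overlapped no protein-coding gene, with the nearest starts, of Zfp36l1 and Ubash3b, 77.8 and 417 kb away. Both replicates' own lists covered each of these, with 76045 and 86514 bp in the Cstad domain and 87251 and 95670 bp in the Npvf domain.

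In all, 14797 domains were formed, 7012 of them from at least 2 peaks. Other nearest genes among the first 25 were Ski, a repressor in TGF-beta signalling whose loss gives facial clefts, Zfhx3, Ncor2, Src, Dusp7, Vgll4, Haao, Capzb and Bahcc1. None of the 25 nearest genes belonged to a fixed list. Of these 25 domains, 23 overlapped a domain of the first 25 in replicate 2's own list, 21 in replicate 1's, 22 in the pooled list and 18 when peaks were joined at 5 kb or domains ranked by covered length. No test was run on the domains.

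The strongest distal peaks lay in an intron of Bicral (chromosome 17, 46855317 to 46859382, enrichment 54.2), near Chd2, a chromatin remodeller gene (chromosome 7, 73556706 to 73560043, 51.6), and near Sirt4 (44.9). An intron of Dnm3 held the next (chromosome 1, 162214583 to 162221644, 40.5), followed by intergenic peaks whose nearest starts were those of Ppm1h (38.6, 87.5 kb away), Zfp869 (36.1, 5.54 kb), Cplx2 (35.9, 66.6 kb), Rps6ka1 (35.6, 55.2 kb), Ubash3b (34.7, 420 kb) and Tex44 (34.6, 13.2 kb). Positions here refer to protein-coding genes only, so some of these distal peaks may be promoters of non-coding genes.

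Recognition sequences of RUNX, FOX, MEF2 and E-box factors were denser in distal peaks than in windows of the same width, chromosome and GC content. RUNX sites, bound by regulators of skeletal development, were 1.32-fold as dense (mean over autosomes 1.33 ± 0.136, SD, n = 19 autosomes), and above 1 on all 19 autosomes; the reversed string gave 0.94. FOX sites had 1.34 (1.35 ± 0.181), with 1.15 for the reversed string, and the E-box CAGCTG 1.3 (1.31 ± 0.103), with 0.986. MEF2 sites had 1.77 (1.93 ± 0.801, above 1 on 18 autosomes), with 1.10. TAATTA, the homeodomain palindrome that factors such as those of the Alx, Prrx, Msx and Dlx families bind, had 1.16 (1.16 ± 0.104), with 0.937. The E-box CAGATG of the TWIST type had 1.0615 (1.07 ± 0.051), with 0.789, and TEAD sites 1.12 (1.12 ± 0.0707), with 0.962.

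TFAP2 sites had 1.2 (1.21 ± 0.0953) with 1.15 for the reversed string, LEF/TCF sites 1.26 (1.3 ± 0.21) with 1.21, and PBX-HOX sites 1.13 (1.15 ± 0.141) with 1.13. For these 10 of 24 motifs the mean over autosomes exceeded 1 by more than the SD over autosomes. Their ratio also exceeded that of the reversed string, for PBX-HOX only beyond the digits printed. This rule was set after the ratios were seen. SOX sites had 1.13 but the reversed string 1.21. Sites of GRHL, an epithelial factor, had 0.894, GATA 0.923, MEIS 0.861, CTCF 0.786, nuclear receptor DR1 0.901, AP-1 1.04, GLI 1.08 and HNF4 1.01. Single NFI sites had 1.07, with 1.40 for the reversed string. Rare motifs gave 52 matches in peaks against 16 in matched windows for paired NFI sites, 52 against 37 for NRF1 and 0 against 2 for HNF1; ETS sites had a ratio of 1.64 (2.21 ± 1.40). The number of motifs meeting the rule was 5 among peaks with a −log10 q of at least 10 and 6 among the 20000 peaks of highest enrichment; TEAD, FOX, RUNX and CAGCTG met it in both, and at the other settings the number was 8 to 11. MEF2 did not meet it among the 20000 highest, within 500 bp around the summit or among peaks found in both lists. CAGATG and TAATTA did not meet it at a −log10 q of at least 10, CAGATG did not in replicate 1's own list, and TAATTA did not in the pooled list. LEF/TCF, TFAP2 and PBX-HOX did not meet it in either of the 2 stricter sets, LEF/TCF did not with matching on CpG as well, LEF/TCF and PBX-HOX did not among peaks found in both lists, and PBX-HOX did not in replicate 1's own list. Gained were NFI in replicate 2's own list and ETS among peaks found in both lists.

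An E-box followed 4 bp later by TAATTA recurred in distal peaks. A composite element of these sites is known from craniofacial mesenchyme, where TWIST and homeodomain factors bind together, and all spacers from 0 to 20 bp in both E-box orientations were scanned. CATMTG followed by TAATTA occurred 27 times at 4 bp (Poisson 95% interval 17.8 to 39.3), against a median of 7 at the other 20 spacers, where the highest count was 11; matched windows had 7 at 4 bp. CAKATG followed by TAATTA occurred 16 times at 4 bp (9.1 to 26), against a median of 5.5 and a highest other count of 11; matched windows had 11. CATATG belongs to both strings, so the sites were 33 in number, in 33 peaks. By E-box, CATCTG had 17 at 4 bp (highest other 8), CATATG 10 (highest other 6), and CAGATG 6, where its highest other count was 7. CATCTG is CAGATG read on the opposite strand, so the counts of 17 and 6 belong to opposite orientations of the same E-box.

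The strongest peak with such a site was the Dnm3 peak named above, which holds CATATGGAACTAATTA at 162216904 to 162216919. Others lay near Tex44 (CATATGAATTTAATTA, chromosome 1, 86464801 to 86464816), within Mmp14, a matrix protease gene (CATCTGGAGGTAATTA, chromosome 14, 54443758 to 54443773), and 158 kb from Gas1 (CATATGAAAATAATTA, chromosome 13, 60018920 to 60018935). The genes Mmp14 and Gas1 were chosen here after their sites were seen. In replicate 1's own list CAKATG pairs numbered 9 at 4 bp and 10 at 0 bp, so 4 bp did not stand out there, nor within 500 bp around the summit, where the count was 9 at 4 bp and the highest other count 9. CATMTG pairs numbered 23 and 30 at 4 bp in the own lists of replicates 1 and 2, with highest other counts of 11 and 14.

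**Figure D4:**
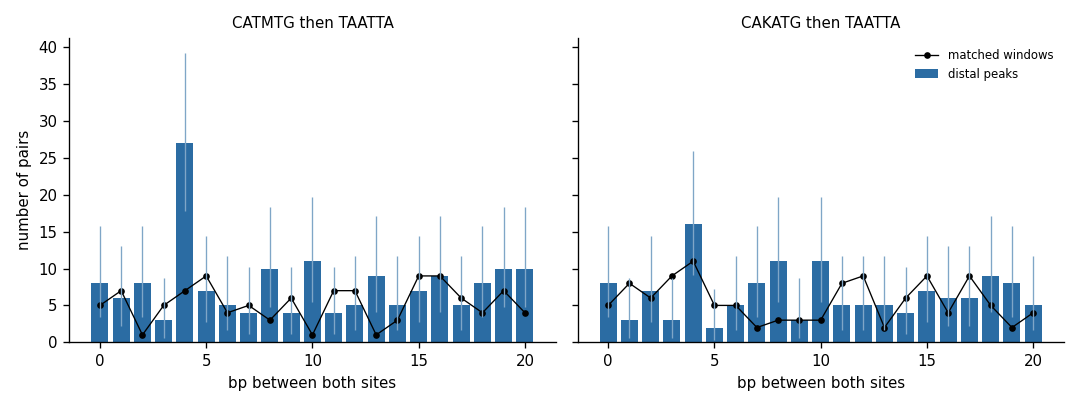
Number of E-box and TAATTA pairs (vertical axis) by the bp between both sites (horizontal axis) in distal peaks (bars, with Poisson 95% intervals) and in windows matched on GC content (line), for CATMTG (left) and CAKATG (right). At 4 bp the bars reach 27 and 16, and at other spacers at most 11.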

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

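All tests of explanations here were chosen after the peak lists were first read, and the test of GC content as the whole cause, the test of chance in the spacing scan and the counts by E-box were chosen only after the result was seen.

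Peaks were also called on contigs outside the assembled chromosomes, which are unplaced or assigned to chromosome 4 or X without a position. They were counted in the overlap of the replicates and in the retention of pooled peaks, and left out of the comparisons by location, gene, motif and chromosome. Replicate 1 had 12 such peaks on 6 contigs, replicate 2 had 5 on 4, the pooled list 13 on 7 and the replicated list 8 on 5, with enrichment of up to 32.0. They stood out because they are a signal that the other comparisons do not cover.

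Chromosome X had 4.34 replicated peaks per Mb, where the lowest autosome had 15.0. Fewer active genes on X would leave the number of distal peaks per gene with a promoter peak in the autosomes' range, but it was 0.99 on X and at least 2.21 on the autosomes, which argues against that account as the whole cause. The share of genes with a promoter peak was also lower on X, at 32.91%. On the autosomes it had a median of 55.08% and was at least 42.35%. A part for fewer active genes is therefore left open. The low GC content of X predicted 8.37 peaks per Mb against 4.35 observed, a ratio of 1.927, where the same ratio reached at most 1.19 on an autosome, so GC alone falls short; its part in the difference cannot be told apart, since the ratio lay between the limits set in advance. Promoter enrichment on X was lower, its 90th percentile 0.616 and its median 0.836 of the autosome medians, in line with a hypothesis that X carries less signal per cell because each cell has a single active copy; distal enrichment, with a 90th percentile 1.242 and a median 1.10 of the autosome medians, goes the other way and may reflect that only strong peaks passed the caller on X. Neither this nor whether reads align less well to X was tested.

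E-box and TAATTA pairs 4 bp apart are a candidate composite element. Even draws of the same total over the 42 arrangements gave a count as high in a share of 1e-04, the smallest 10000 draws can give. The draws take pairs as evenly spread and independent. CATATG pairs count in both orientations, and spacers outside peaks were uneven, as given below. The draws therefore cannot decide on chance. Copies of a repeat with closely alike flanks are argued against: 0.0% of the 33 sites shared 70% or more of 20 bp on both sides with another. The flanks were compared without gaps and no repeat annotation was used, so diverged or gapped copies are left open. Pairs with TAATTB, which are other sites, were also more frequent at 4 bp, by at least 2.788-fold over the median of the other spacers in both arrangements, in line with a fixed spacer, although CATMTG with TAATTB was nearly as frequent at 0 bp (48 against 50), as it was in windows 10 kb away (48), where CAKATG with TAATTB also reached 53 at 20 bp, so single spacers can be frequent outside peaks. CATCTG is CAGATG read on the opposite strand, so the counts by E-box compare orientations of the same E-box for these strings. Read as CATCTG before TAATTA, it had 17 pairs at 4 bp. Read as CAGATG, it had 6 at 4 bp and up to 7 elsewhere. The preference may thus hold for CATATG and for the CATCTG orientation of this E-box. These data cannot show which proteins bind.

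Of the replicated peaks, 19.7% had no overlapping peak in both replicates' own lists. Of these, 17.49% lay within 200 bp of a peak of every replicate they lacked, between the limits set in advance, so a part for a looser rule that counts nearby peaks is left open. As the whole rule it is argued against, since 664 pooled peaks that overlap a peak in both lists by at least 1 bp were dropped. All 40564 pooled peaks with at least 50% of either peak covered in both lists were kept, so the 664 lacked such cover. Such a 50% rule is not the whole rule either, since 10384 replicated peaks lacked that cover. A second criterion that follows peak strength is also possible: a kept peak had higher enrichment than a dropped one with an area under the curve of 0.815. No biological explanation was tested here.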

How the results depend on the processing

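The alternative that kept only replicated peaks found in both replicates' lists, counting neighbouring list members once, and the spacing scan on stricter peak sets, around summits and with CpG matching were chosen only after the data were seen; the others were fixed before. With 50% of the own length asked for, 43.3% of replicate 1's and 39.2% of replicate 2's peaks were shared, with 50% of both peaks 28.9% and 29.7%, at a −log10 q of at least 2 58.8% and 53.1%, at 10 89.2% and 76.2%, and among the 20000 highest 74.6% and 71.2%. Rho was 0.718 and 0.763 at those q limits, 0.774 with 50% of both peaks and 0.715 on −log10 p. Of pooled peaks, 54.3% and 99.9% were kept at those limits. The promoter share was 18.7% to 18.8% in the replicates' own lists, 15.5% in the pooled list, 50.9% at a −log10 q of at least 10, 47.6% in the 20000 highest, 30.3% among peaks found in both lists, 30.5% within 2.5 kb and 24.1% with 1 start per gene. The number of lists past the test went from 12 to 16 for promoters, 14 as reported, and from 9 to 14 for distal peaks, 10 as reported. The facial epithelium list, 52% and not called, passed below other genes with 16% at a −log10 q of at least 10; the cause was not tested. Motifs meeting the rule numbered 5 at a −log10 q of at least 10 and 6 in the 20000 highest, which hold fewer peaks, and 8 to 11 elsewhere. The excess of CATMTG pairs at 4 bp over the median of other spacers, 3.86, was 3.83 to 5.0 in the replicates' own lists, 3.05 in the pooled list, 6.67 at a −log10 q of at least 10 and 7.0 in the 20000 highest; that of CAKATG pairs, 2.91, was 1.80 to 2.15, 6.50 and 4.33, with 2.35 in the pooled list, 2.25 around summits and 3.20 in peaks found in both lists. Of the first 25 domains, 18 to 23 kept a place. Of single motif ratios 126 moved by more than their spread and 63 did not; of covered lengths of named genes, 224 and 192. The causes of these moves were not tested, and unknown depth limits what the weakest peaks can show.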

Other observations

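The list of imprinted genes and all tests on it were chosen only after the distal domains were seen, as was the distance of 200 kb used for their neighbours.

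Several of the first-ranked distal domains lay next to imprinted genes, which are expressed from the copy of 1 parent and often control embryonic growth. Of the 25 first domains, 4 had an imprinted gene within 200 kb. The share over all domains was not counted, so whether this is an excess is unknown. The domain nearest Tnnt3 on chromosome 7 overlapped H19 and lay beside Igf2 and Ins2, that at Ddc on chromosome 11, itself imprinted, lay beside Grb10, that at Src on chromosome 2 held Nnat and Blcap, and that at Cpa5 on chromosome 6 lay beside Mest and Copg2. A gene of a fixed list lay within 200 kb of 2 domains, Prrx2 and Klf1. Within 100 kb of their starts, Ddc had 52 distal peaks, Mest 38, Dlk1 37, Nnat 33 and Igf2r 26, while the imprinted genes Ndn, Magel2, Snrpn and Ube3a had 0. These genes were chosen after their values were seen.

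A hypothesis from this pattern is that imprinted genes have more distal acetylated regions in the face than matched genes. Of 52 imprinted genes listed, 51 were among the protein-coding genes used here and had 10.7 distal peaks on average, against 3.90 in matched random lists. H19, which is non-coding, was left out. Dlx5, with 12 distal peaks, is among these genes and also in the mandibular and bone lists, and no test without it was run. Since that mean includes the domains that prompted the list, the test was then made stricter: without genes near the first 25 domains, and with neighbours counted once, the remaining 28 genes had 7.25 against 3.76 (95% of random lists 2 to 6.04), at percentile 99.69. This followed a looser test on all members, which gave percentile 100. Lists matched on promoter enrichment gave percentile 99.74, but that matching hardly moved the random mean (3.74), so whether strong promoters play a part is left open. Random lists were not matched on non-coding genes, whose promoters count as distal here, so their part in the difference was not tested. The result may suggest a property of imprinted regions, but it was found and tested on the same peaks, and another tissue's peaks would be needed to tell whether it belongs to the face.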
